A study of Homo sapiens with 118 samples.

How the data were processed

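Plasma microRNAs were measured in 118 libraries with the HTG miRNA whole transcriptome assay, in which probes capture mature miRNAs and the captured probes are amplified, indexed and sequenced. Per the labels, blood was drawn into Streck or EDTA tubes, plasma was kept frozen, and libraries were made by PCR and cleaned on beads. The labels do not say which tube a sample came from, and they name no batch, date or plate. Per the labels, 73 libraries came from cancer-free donors, 31 from primary glioblastoma (GBM) and 13 from recurrent GBM. The labels of 1 further library contradict each other on its group, so it entered no comparison. Libraries were taken as separate donors, which holds only as far as the labels say.

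The authors deposited a raw count for each of 2083 miRNA probes in each library, per the name of the sheet. The aligner or counting program, its version and the reference used are not given in the sources used here. The authors also deposited a table of normalized signal, on a sheet whose name says that DESeq2 was used, with no version. Each value of this signal table equalled the deposited count divided by 1 factor per library, within a relative deviation of 3.6e-08. These factors ranged from 0.133 to 7.55. The normalized signal was used only for this check, and every comparison started from the deposited counts. The table held 0 duplicate miRNA names, 0 missing values, 0 columns without a sample and 0 probes named as controls.

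Counts of GBM and cancer-free libraries were compared with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr on the groups, TMM scaling, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. The filter kept 1955 miRNAs for GBM against cancer-free plasma. A fit with 3 groups kept 2082 miRNAs and gave primary GBM against cancer-free, recurrent GBM against cancer-free, and recurrent against primary GBM. In the report, higher, lower, rose and fell refer to that threshold, fold changes are on the log2 scale, and the error after ± is a standard error for a fold change and an SD for a level. Levels are log2 CPM (counts scaled to a common library total) after TMM scaling.

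Lists of miRNAs were tested with limma 3.58.1. The camera test with a preset correlation of 0.01 compared a list with all other miRNAs and was repeated with an estimated correlation. The fry test asked whether the members of a list moved on balance in 1 direction, and its mixed version whether they changed in either direction. The 15 lists were erythrocyte, platelet, leukocyte, brain-enriched, GBM tissue oncomiRs, GBM tissue tumour suppressors, circulating glioma markers, the miR-17-92 and paralogous clusters, the let-7 family, liver, striated muscle, the 14q32 cluster, the C19MC cluster, and late-numbered and early-numbered miRNAs. Late-numbered miRNAs have a number above 3000 in their name and early-numbered ones a number below 500. List adjustment ran over the 15 lists of a contrast. The list members came from general knowledge, without a source in the box, and they overlap: miR-451a, for example, is in the erythrocyte list and in the haemolysis index.

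The haemolysis index was log2(CPM + 1) of miR-451a minus that of miR-23a-3p. The index and log2 total counts were compared between groups with a two-sided permutation test of 100000 resamples. Separation of the groups was measured as the area under the receiver operating characteristic curve (AUC) of an L1 logistic regression on log2(CPM + 1), with 10 folds repeated 10 times, 3 inner folds for the penalty and 100 permutations of the labels, in scikit-learn 1.9.0. The smallest p that 100 permutations can give is 0.0099. The correlation of primary and recurrent effects was set against simulated groups without change that shared the cancer-free libraries, and against contrasts that each used a separate part of the cancer-free libraries.

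The named miRNAs followed a rule. For GBM against cancer-free plasma it took, among called miRNAs with a mean level above the median of those tested, the 10 largest rises, the 10 largest falls and the 5 smallest p in each direction. For recurrent against primary GBM it took the 5 smallest p in each direction. It added the 3 members of each list with the smallest p, miR-451a, miR-23a-3p and the 3 most abundant miRNAs. The groups, comparisons, tests, lists and this rule, as well as the alternatives not listed below as later additions, were chosen before the data were examined. Any other miRNA named was chosen after its values were seen.

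Library structure was described after seeing the data. Near-empty libraries are those in which fewer than 1000 of the 2083 miRNAs had a count above 0. A first attempt to divide the cancer-free libraries counted single miRNAs with an AUC of at least 0.95 between the libraries before and after a break. It put the break elsewhere, at 54 and 19 libraries with 46 such miRNAs, against 33 at the break used below. Of the 46, 0 were higher before the break, so no pairs could be formed, every library was left unclear and the attempt was dropped. The division used rests on the order of miRNA pairs within a library, for miRNAs with a median CPM above 45. A pair counted when the share of libraries with 1 order differed by at least 0.95 between the cancer-free libraries before and after a break in the order of their title numbers. The best break had 1937 such pairs over 567 miRNAs and divided the cancer-free libraries into 44 and 29. In 20 shuffles of the order, the highest number of such pairs at any break was 0. A score from 67 disjoint pairs, above 0.6 for set 1 and below 0.4 for set 2, then placed the GBM libraries, without use of miR-4525. The pairs include miR-4706, miR-3937, miR-1247-3p, miR-3917, miR-4707-5p, miR-4530, miR-3663-5p, miR-4436a and the let-7 list member let-7a-5p. Values of these miRNAs within a set, and their differences between sets, are not independent of the placement. Pairs with equal counts in a library count towards set 2. Over the other pairs alone, the 3 near-empty libraries of set 2 scored 0.328 to 0.356, still below the limit. Of 36 cancer-free libraries held out from the choice of pairs, 35 fell in their own block. The break itself had been chosen with these libraries included, so this does not test the break. The sets are not groups of the study, and the labels do not explain them.

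The alternatives were DESeq2 size factors, library size alone, upper quartile scaling and TMM without the 5 most abundant miRNAs; no filter and a filter at 100 counts; DESeq2 1.42.0 and limma voom with sample quality weights in place of edgeR; a replicate block on title numbers; the haemolysis index or log2 total count as covariate; an absolute log2 fold change of at least 1 as a further threshold; libraries with less than 0.25 of the median total left out; other pseudocounts, red cell miRNAs, models and feature sets for the single values. Added after seeing the data were fits without near-empty libraries, within each set, with the set or the background level (median CPM) as covariate, models trained on 1 set and tested on the other, and an interaction of GBM and set. The run of title numbers among GBM libraries without miR-4525 counts was also tested after seeing the data, by shuffling the numbers. A filter on control probes was not run because the table holds none.

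The edgeR fit was tested on simulated counts with 200 changed miRNAs. For GBM against cancer-free plasma, with 1955 miRNAs, it recovered 41.8% of 1.5-fold, 80.6% of 2-fold and 83.3% of 4-fold changes, and 2.84% of calls were false. For recurrent against primary GBM, with 2082 miRNAs, it recovered 5.97%, 25.4% and 86.4%, with 6.02% of calls false. Apart from these changes each miRNA had 1 mean level, without library sets or near-empty libraries, so these shares of false calls do not carry over to the real libraries. Random splits of the real libraries into groups of the same sizes called a median of 33 miRNAs for GBM against cancer-free plasma. For recurrent against primary GBM the median was 107. Total counts per library ranged from 454518 to 6702324. Reads amplified by PCR without molecular identifiers are not independent molecules, so no interval was taken from the read counts of 1 library. SEs and SDs carry the variation between libraries, and Wilson intervals are on shares of called miRNAs. Between libraries of 1 group, counts of at least 10 varied far beyond counting error: the lowest chi-square per degree of freedom over 3171 pairs of libraries was 11.86. Positions of miRNA hairpins are from GENCODE release 29 on GRCh38, matched by hairpin name, and the files themselves give no coordinates. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were also used.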

Results

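Mature miRNAs were counted in plasma from 73 cancer-free donors and 44 people with glioblastoma (GBM), of whom 31 had primary and 13 recurrent disease. Total counts per library had a median of 787521 in cancer-free plasma (454518 to 1476120), 926912 in primary GBM (501183 to 6702324) and 706255 in recurrent GBM (488790 to 1428572). Of 2083 miRNAs, a median of 2056 had a count above 0 in cancer-free plasma (1698 to 2083) and 2022.5 in GBM (631 to 2083). The most abundant miRNAs were miR-451a with 14.4% ± 10.9 of counts (SD over the libraries of these groups), miR-3197 with 12.9% ± 9.30 and miR-6126 with 11.6% ± 8.35. miR-3197 had a median share of 6.89% in GBM and 15.1% in cancer-free plasma, and miR-451a of 14.7% and 11.9%. miRNAs with a number above 3000 in their name took 45.9% ± 17.2 of counts.

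In 4 GBM libraries (3 primary and 1 recurrent) and 0 of 73 cancer-free libraries, fewer than 1000 miRNAs had a count above 0. These near-empty libraries had a median of 730.5 detected miRNAs. miR-6126 took a median of 49.1% of their counts against 9.74% in the 113 others, and miR-4706 took 18.8% against 0.0496%. miR-451a was at 0.0205% in them against 13.1%, and miR-3197 at 0.0867% against 12.3%. A total in the usual range therefore went with few detected miRNAs in these libraries.

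**Figure D1:**
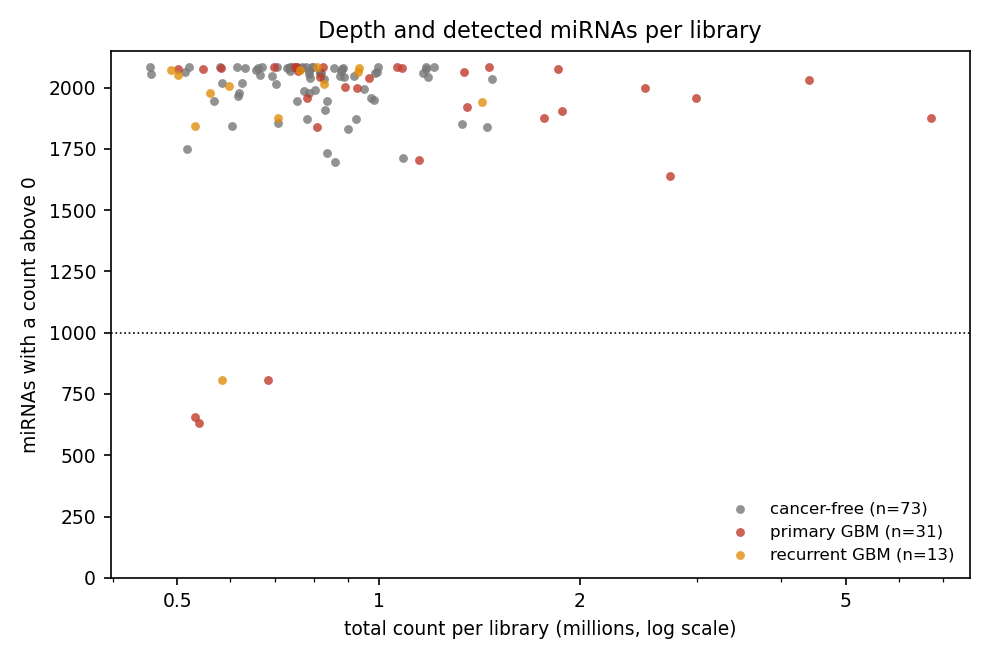
Total count per library (log axis) against the number of miRNAs with a count above 0, 1 point per library, for 73 cancer-free, 31 primary GBM and 13 recurrent GBM libraries; the dotted line is at 1000 miRNAs. The 4 GBM libraries under the line had between 631 and 808 detected miRNAs and totals between 530537 and 682923.

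The cancer-free libraries fell into 2 sets of 44 and 29 by the order of miRNA pairs within each library, and GBM libraries were placed by the same score. Set 1 held 44 cancer-free and 29 GBM libraries (17 primary, 12 recurrent). Set 2 held 29 cancer-free and 10 GBM libraries, all primary, 3 of them near-empty. The other 5 GBM libraries (4 primary, 1 recurrent) were unclear, and the fourth near-empty library, from recurrent GBM, was among them. No GBM library of set 2 had a score in the range of its cancer-free libraries (0 to 0.0149): 7 lay between 0.0746 and 0.239, and the 3 near-empty ones at 0.313, nearest the limit of 0.4. In set 1, GBM libraries had a median score of 0.821 (0.657 to 0.925) and cancer-free libraries of 1.0 (0.761 to 1.0). In each set GBM libraries thus lay towards the other set, so a comparison within a set does not fully remove the set difference. A criterion on single miRNAs had placed the break between cancer-free libraries elsewhere, so values within a set depend on how the sets were defined. Between cancer-free libraries of set 2 and set 1, 573 miRNAs were higher and 730 lower of 1919 tested. Of the miRNAs called between GBM and cancer-free plasma, 369 also differed between these cancer-free libraries, 312 of them in the direction of GBM. Values within each set are therefore given beside the pooled ones.

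The main question was which plasma miRNAs separate people with GBM from cancer-free donors. miR-5739 and miR-3180-3p rose in GBM plasma in both sets. miR-5739 was at 10.74 ± 2.06 log2 CPM (SD, n = 44) in GBM and 8.6 ± 0.88 (n = 73) in cancer-free plasma, and 40 of 44 GBM libraries lay above the cancer-free median. Its fitted log2 fold change was 4.73 ± 0.39 (adjusted p = 3.2e-20), which exceeds the difference of the mean levels because a few libraries were extreme: without the near-empty libraries it was 2.34 ± 0.23. Within set 1 it was 2.19 ± 0.29 (adjusted p = 3.4e-09) and within set 2 3.73 ± 0.45 (adjusted p = 3.1e-09), or 2.09 ± 0.34 in set 2 without near-empty libraries. The miR-5739 hairpin lies on chromosome 22 at 28459869 to 28459948 (GRCh38), within an intron of TTC28 on the opposite strand.

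miR-3180-3p rose by 1.96 ± 0.21 (adjusted p = 7.4e-13), with 39 of 44 GBM libraries above the cancer-free median and levels of 7.20 ± 2.01 and 5.92 ± 0.60 log2 CPM. Within set 1 the fold change was 2.26 ± 0.20. Within set 2 it was 1.60 ± 0.42 (adjusted p = 0.0019) with 7 of 10 GBM libraries above the median, although the mean levels were 6.25 ± 3.55 and 6.34 ± 0.52 because near-empty libraries were low. The effects in the sets were not shown to differ (difference -0.53, adjusted p = 0.357). miR-3180, whose name matches the same hairpin genes as miR-3180-3p, rose by 1.83 ± 0.20 with 37 of 44 above. Counts of the 2 probes cannot be fully told apart. The 5 annotated hairpins that match by name lie on chromosome 16, at 2135977 to 2136129, 14911220 to 14911313, 15154850 to 15155002, 16309879 to 16309966 and 18402178 to 18402271. Which of them gives which mature miRNA was not examined.

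miR-4706, in an intron of FNTB on chromosome 14 at 65044688 to 65044769, rose by 4.22 ± 0.57 (adjusted p = 4.2e-09) with 30 of 44 libraries above the cancer-free median. Its rise was 1.52 ± 0.26 within set 1 and 5.39 ± 0.54 within set 2, a difference of 3.66 (adjusted p = 2.96e-08), and 2.49 ± 0.51 without near-empty libraries. Of 17 alternatives 16 kept the call of miR-4706 and 1 did not, with fold changes from 0.11 to 7.97. miR-3937 rose by 2.69 ± 0.31 (adjusted p = 6.7e-12, 30 of 44 above), by 2.75 ± 0.33 within set 1, and was at -0.01 ± 0.49 within set 2, where it was not called. The 2 sets differed in this effect by -2.61 (adjusted p = 0.000898). The other 7 of the 10 largest rises were not called within set 1. miR-124-3p, a brain-enriched miRNA, rose by 2.97 ± 0.37 (adjusted p = 1.5e-10) in the pooled fit with 20 of 44 libraries above the median, by 2.68 ± 0.39 within set 2, and was at -0.02 ± 0.27 within set 1. miR-4292 rose by 2.07 ± 0.29 (26 of 44 above) and stood at 0.34 within set 1. miR-6081 (2.36, 14 of 44 above), miR-150-5p (2.27, 19 above), miR-6838-3p (2.17, 17 above), miR-1247-3p (2.14, 20 above) and miR-3917 (1.98, 21 above) were called with no more than 21 of 44 libraries above the cancer-free median. Within set 1 these 5 lay between -0.27 and 0.13. miR-150-5p was at -0.54 within set 2. The effect was larger in set 2 than in set 1 for miR-124-3p (2.68), miR-4292 (2.69), miR-6081 (3.81), miR-6838-3p (3.67), miR-1247-3p (2.91) and miR-3917 (2.72), with adjusted p of the difference of at most 2.12e-06, and was not shown to differ for miR-150-5p (adjusted p = 0.547). miR-1247-3p was at 0.17 without near-empty libraries (adjusted p = 0.74). miR-4706, miR-3937, miR-1247-3p and miR-3917 belong to the pairs that placed the libraries in the sets. Their values within the sets and their differences between sets are therefore not independent of that placement.

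Among the falls, miR-4525 changed most, by -3.11 ± 0.53 (adjusted p = 2.3e-06), with 32 of 44 GBM libraries below the cancer-free median. Its probe, for a hairpin in an intron of RAB40B on chromosome 17 at 82668233 to 82668307, gave 0 counts in 13 GBM libraries (12 primary, 1 recurrent) and in 0 of 73 cancer-free libraries. These 13 libraries included 9 of the 10 GBM libraries of set 2 and 0 of the 29 of set 1, and 1 of them had the highest total of the series, 6702324. They have consecutive title numbers, where the longest run in 1000 shuffles of the GBM title numbers was 7, and they include all 4 near-empty libraries. The probe of miR-128-2-5p also gave 0 counts in all 13, and in 15 GBM and 3 cancer-free libraries in all. Within set 1 the fold change of miR-4525 was -0.08 ± 0.30 (adjusted p = 0.86). Within set 2 it was -7.63 ± 1.28, a fitted value that depends on the prior count since most GBM libraries there were at 0, and the sets differed by -7.66 (adjusted p = 1.66e-09). miR-8084 fell by 2.05 on the log2 scale (SE 0.43, adjusted p = 9.4e-05) with 37 of 44 below the cancer-free median, and by 2.17 within set 1. miR-606, in an intron of LRMDA on chromosome 10 at 75552458 to 75552553, was at -1.55 ± 0.36 (adjusted p = 0.000511, 38 of 44 below) and at -1.68 within set 1. miR-3648 (-1.71, 33 below), miR-1468-3p (-1.56, 32 below), miR-4423-3p (-1.38, 37 below), miR-3914 (-1.37, 37 below), miR-3910 (-1.33, 32 below), miR-3690 (-1.13, 28 below) and miR-5584-5p (-1.01, 34 below) lay between -2.74 and -1.18 within set 1. Of these, miR-3648, miR-1468-3p, miR-3910, miR-3690 and miR-5584-5p were tested and not called within set 2, and miR-1468-3p (0.19) and miR-3910 (0.59) had the opposite sign there. The difference between sets passed the threshold for miR-3648 (2.69), miR-1468-3p (2.26), miR-3910 (2.48) and miR-5584-5p (0.99), and not for miR-3690 (0.77, adjusted p = 0.253). miR-8084, miR-606, miR-4423-3p and miR-3914 were too low to be tested within set 2 alone, where 8, 7, 5 and 8 of 10 GBM libraries lay below the cancer-free median. In the fit with both sets their effects were not shown to differ (adjusted p from 0.183 to 0.587). miR-3175 (-1.54, 30 below) was at -0.36 within set 1 and -2.25 within set 2, a larger fall in set 2 (difference -1.78, adjusted p = 0.0108). miR-711, at an exon of COL7A1 on chromosome 3 from 48578902 to 48578977, was at -1.10 ± 0.25 (adjusted p = 0.000366, 38 of 44 below), at -0.58 within set 1 and at -1.87 within set 2 (difference -1.20, adjusted p = 0.0236).

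**Figure D2:**
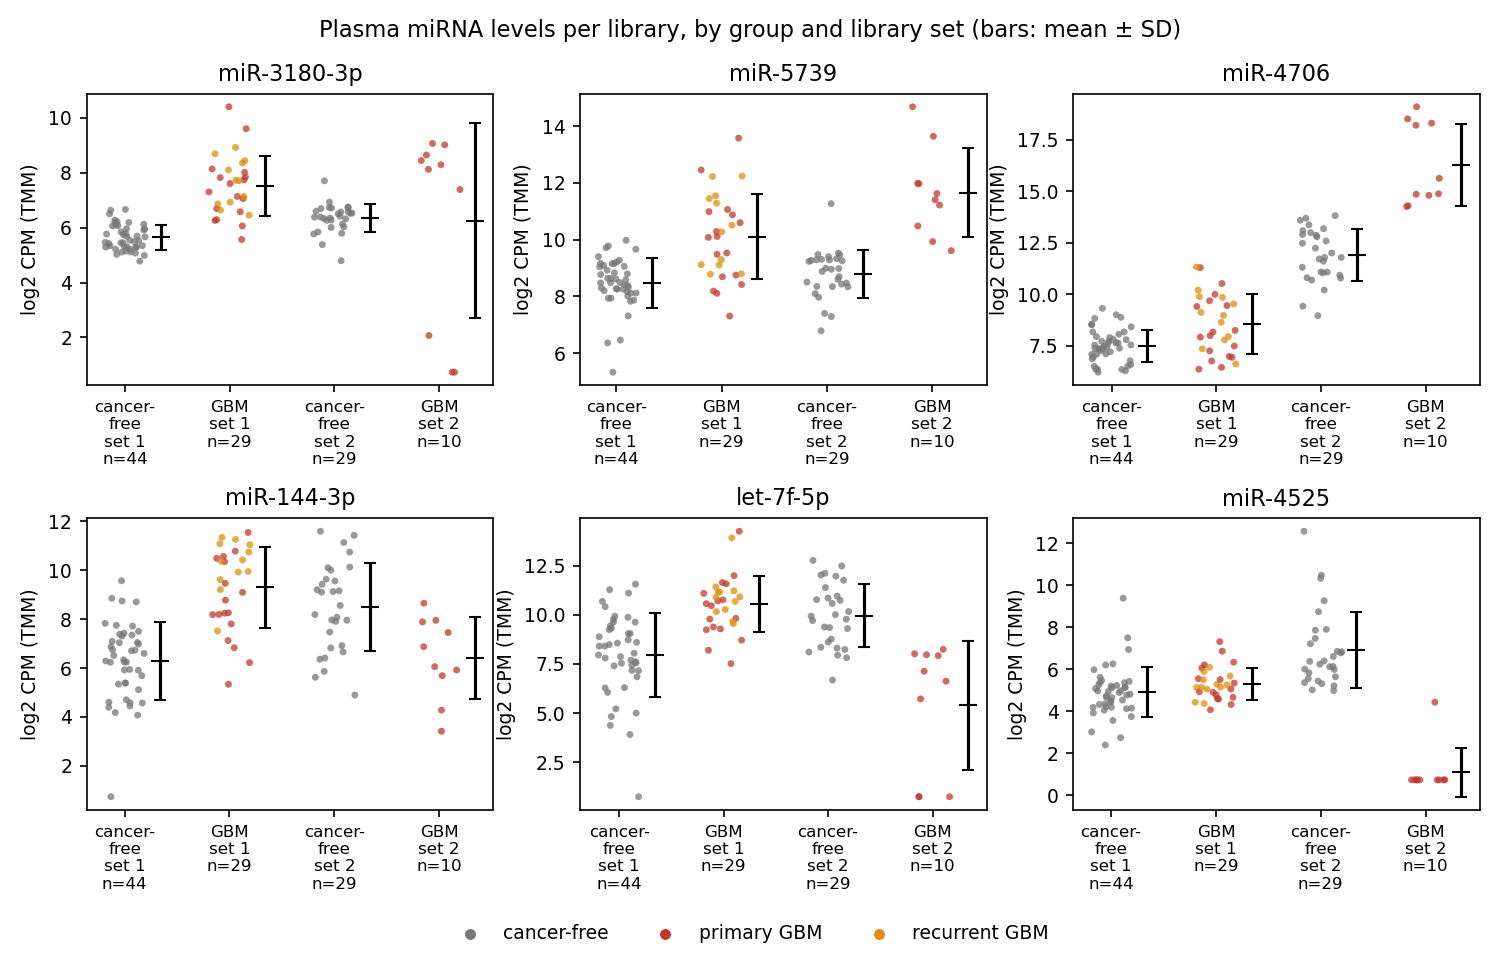
Level (log2 CPM after TMM scaling, 1 point per library; bars are mean ± SD) of miR-3180-3p, miR-5739, miR-4706, miR-144-3p, let-7f-5p and miR-4525 in cancer-free and GBM plasma of set 1 (44 and 29 libraries) and set 2 (29 and 10). miR-5739 rose in both sets (2.19 and 3.73), while let-7f-5p was at 2.32 within set 1 and -3.68 within set 2, and miR-4525 at -0.08 and -7.63.

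In GBM against cancer-free plasma, 242 miRNAs were higher and 244 lower of 1955 tested (49.8% higher; 731 at an unadjusted p under 0.05). The split between higher and lower depended on scaling. It was 221 and 393 (36% higher) with DESeq2 size factors, which moved the median of all miRNAs by -0.22 log2. With library size alone it was 65 and 931 (6.53%, shift -0.71), and with upper quartile scaling 366 and 131 (73.6%, shift 0.039). Within set 1, 295 miRNAs were higher and 346 lower. Of the 242 higher in the pooled fit 72 were also called higher there and 15 lower, and of the 244 lower 194 were also called lower. Within set 2, 268 were higher and 252 lower, with 172 of the 242 and 20 of the 244 shared, and 12 of the 242 called lower. Without its near-empty libraries set 2 shared 75 of the 242 and 14 of the 244, and 16 of the 242 were called lower. Of the 244, 112 were tested in the whole of set 2 and 105 of these had the same sign, and of the 242, 240 were tested and 204 had the same sign. Without near-empty libraries, 98 of the 242 and 143 of the 244 were called in the same direction. The effect of GBM differed between the sets for 773 of 2083 miRNAs (n = 112 libraries), of which 206 were among the pooled calls, and for 620 miRNAs without near-empty libraries.

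The medians of the blood cell lists had opposite signs in the 2 sets, but no list passed the threshold in either set with an estimated correlation. In set 1 the erythrocyte list had a median log2 fold change of 1.52 with 9 of 11 members higher, and in set 2 of -2.36 with 8 of 11 lower. The let-7 family had 8 of 8 higher in set 1 (median 1.35) and 8 of 8 lower in set 2 (-2.58), and the miR-17-92 clusters 11 of 13 higher (1.28) and 12 of 13 lower (-2.26). The platelet list was at 0.71 with 2 of 10 higher and at -2.20 with 8 of 10 lower, and the leukocyte list at 0.88 with 4 of 10 higher and -1.64 with 7 of 10 lower. Fewer members were lower in set 2 without near-empty libraries: 6 of 11 erythrocyte, 4 of 8 let-7, 5 of 13 miR-17-92, 3 of 10 platelet and 3 of 10 leukocyte miRNAs. All 11 erythrocyte, 8 let-7 and 13 miR-17-92 members had a smaller GBM effect in set 2, with median differences of -3.91, -3.94 and -3.39. Of the let-7 family, let-7a-5p belongs to the pairs that placed the libraries in the sets. These opposite signs of the erythrocyte, let-7, miR-17-92, platelet and leukocyte medians held with DESeq2 size factors, library size alone, upper quartile scaling and TMM without the 5 most abundant miRNAs in each set. With library size alone the erythrocyte list was at 0.93 and -1.64. The list tests held only with the preset correlation. The erythrocyte list had an adjusted p of 8.55e-09 in set 1 and 0.000276 in set 2, against 0.409 and 0.470 with an estimated correlation. With the latter the let-7, miR-17-92, platelet and leukocyte lists had adjusted p from 0.469 to 0.627 in set 1 and of 0.470 in set 2, and the difference between sets had adjusted p from 0.356 to 0.453 for these 5 lists. Without near-empty libraries these values were 0.726 in set 2 and 0.553 for the difference. miR-144-3p was at 3.0 in set 1 and -2.12 in set 2, let-7f-5p at 2.32 and -3.68 (difference -5.89, adjusted p = 1.36e-07), miR-96-5p at 2.90 and -2.82, and miR-451a at 1.21 and -2.80.

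**Figure D3:**
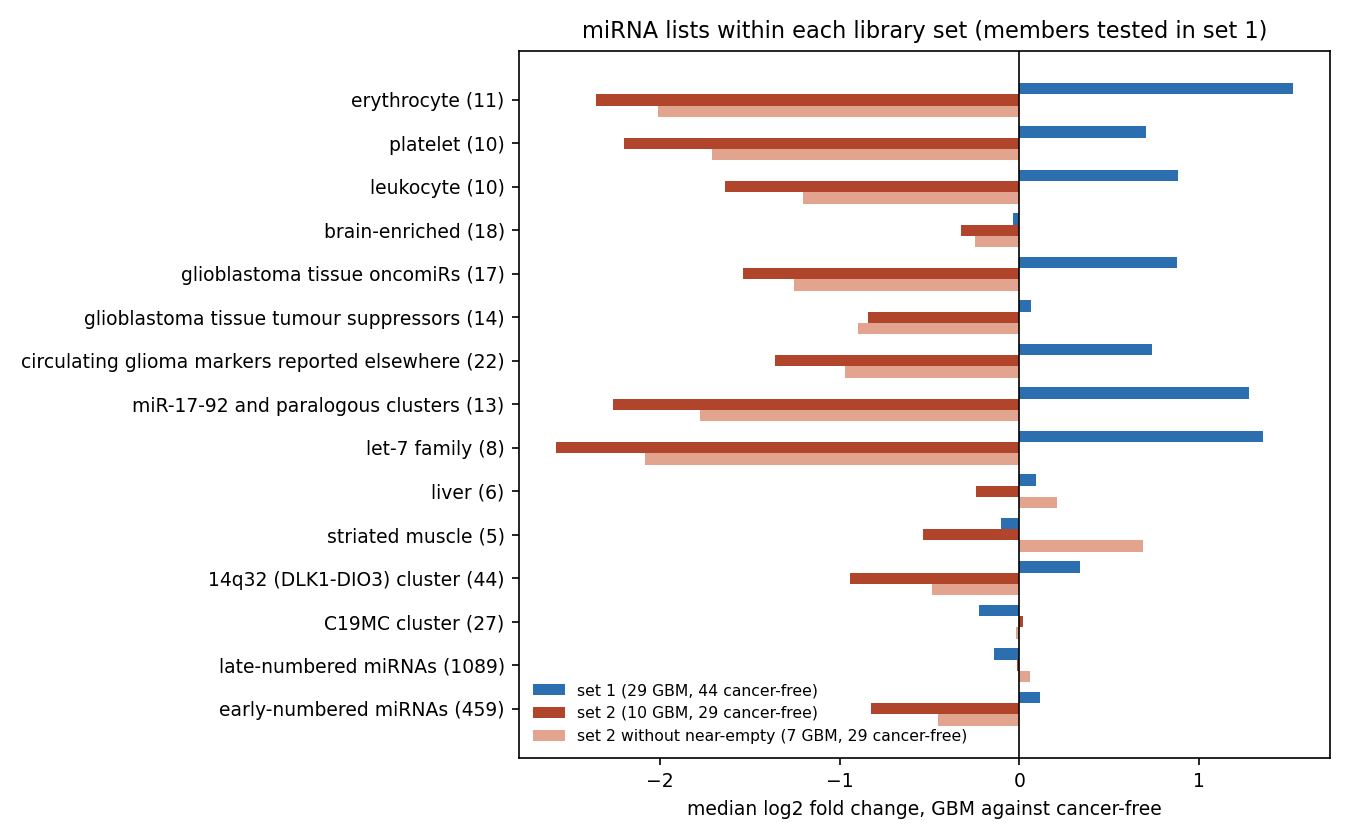
Median log2 fold change of each list in GBM against cancer-free plasma within set 1 (29 and 44 libraries), within set 2 (10 and 29) and within set 2 without near-empty libraries (7 and 29). The erythrocyte list is at 1.52, -2.36 and -2.01, and the let-7 family at 1.35, -2.58 and -2.08.

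Over all libraries, list effects were small. The erythrocyte list had a median of 0.47 with 1 of 11 members higher, also when adjusted over the list alone (camera adjusted p = 0.0129, and adjusted p = 0.887 with an estimated correlation). miR-144-3p was that member, at 1.57 ± 0.38 (adjusted p = 0.000842, 34 of 44 above), while miR-96-5p (0.82) and miR-20b-5p (0.72) were not called. The leukocyte list had a median of 0.79 with 4 of 10 higher, or 5 when adjusted over the list alone (adjusted p = 0.0390, and adjusted p = 0.887 with an estimated correlation). Its members miR-155-5p (1.33, 38 above) and miR-342-3p (1.41) were called higher, although 18 of 44 GBM libraries lay above the cancer-free median for miR-342-3p. The GBM tissue oncomiRs had a median of 0.32 with 2 of 17 higher (1 adjusted over the list alone; adjusted p = 0.0254, and adjusted p = 0.887 with an estimated correlation), and the sign turned to -0.01 with library size alone. The circulating glioma markers had a median of 0.31 with 3 of 22 higher (1 adjusted over the list alone; adjusted p = 0.0318, and adjusted p = 0.887 with an estimated correlation), at -0.01 with library size alone. The miR-17-92 clusters had a median of 0.32 with 0 of 13 called by edgeR, also adjusted over the list alone (adjusted p = 0.0318, and adjusted p = 0.887 with an estimated correlation). miR-182-5p (0.93, 38 above) and miR-15b-3p (0.55, 30 above) were higher, and miR-30a-5p (0.71), miR-29b-3p (0.81), miR-146b-5p (0.73), miR-19a-3p (0.54) and miR-25-3p (0.45) were not called.

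The other 10 lists were not separated from the rest of the miRNAs by camera over all libraries. The platelet list (median 0.08, 0 of 10 called, adjusted p = 0.381) included miR-126-5p at 0.84, miR-197-3p at 0.61 and miR-409-3p at -0.30. The let-7 family (0.18, 0 of 8 called, adjusted p = 0.185) included let-7f-5p at 0.94, let-7e-5p at 0.55 and let-7g-5p at 0.62. The brain-enriched list had a median of 0.03 with 1 of 18 higher and 2 lower (adjusted p = 0.924), the lower ones being miR-132-5p (-0.61, 31 of 44 below) and miR-383-5p (-0.73, 29 below). Its fry direction was down although its mean was 0.14, and its median was at -0.30 with DESeq2 size factors, -0.80 with library size alone and -0.01 with upper quartile scaling. The tumour suppressors (0.28, 1 of 14 higher, adjusted p = 0.381) and the liver list (0.41, 0 of 6 called, adjusted p = 0.461) also had a fry direction opposite to their median. The liver list included miR-885-5p at 0.44, miR-148a-3p at 0.63 and miR-122-5p at 0.54. The striated muscle list (0.17, 0 of 5 called, adjusted p = 0.461) included miR-208b-3p at -0.29, miR-133a-3p at 0.38 and miR-208a-3p at 0.17. The platelet, liver, muscle and tumour suppressor medians turned to -0.22, -0.15, -0.56 and -0.14 with library size alone, and the muscle median to -0.14 with DESeq2 size factors. The 14q32 cluster (0 of 43 called, adjusted p = 0.902) had a median of -0.04, a mean of 0.000113 and a camera direction of up, was at 0.05 with TMM without the 5 most abundant miRNAs, and included miR-758-3p at 0.58, miR-889-3p at 0.48 and miR-485-5p at -0.40. The C19MC cluster (median -0.19, 1 of 25 higher and 4 lower, adjusted p = 0.127, fry down with adjusted p = 0.0539) included miR-515-5p at 0.95 (26 of 44 above), miR-519c-3p at -0.82 (33 below) and miR-515-3p at -0.62 (32 below), each called. Late-numbered miRNAs had 155 of 1056 higher and 157 lower, or 162 and 168 adjusted over the list alone (median -0.10, adjusted p = 0.485). They changed in either direction by the mixed fry test (adjusted p = 1.93e-05) and moved down on balance by the directional one (adjusted p = 0.0177), neither of which compares them with other miRNAs. miR-378f, an early-numbered miRNA, was at 1.45 (adjusted p = 1.4e-06, 26 of 44 above), at -0.10 within set 1 and 2.30 within set 2. Early-numbered miRNAs had 34 of 453 higher and 25 lower, or 28 and 20 adjusted over the list alone (adjusted p = 0.381). Their median was 0.06, but -0.12 with DESeq2 size factors and -0.51 with library size alone, and their fry direction was down. For the platelet, let-7, brain-enriched, tumour suppressor, liver, muscle, 14q32 and C19MC lists, calls adjusted over the list alone had the same counts as over all miRNAs.

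The abundant miRNAs showed little pooled change. miR-451a was at 0.50 (adjusted p = 0.305), miR-3197 at -0.60 (adjusted p = 0.152) and miR-23a-3p at 0.38 (adjusted p = 0.530). miR-6126 was called at 0.84 (adjusted p = 0.0188, 25 of 44 above), but was at -0.03 within set 1 and -0.02 without near-empty libraries. The haemolysis index was 4.07 ± 1.97 (n = 44) in GBM and 4.17 ± 1.73 (n = 73) in cancer-free plasma, a difference of -0.10 (two-sided permutation p = 0.782). Within set 1 the difference was 0.38 (p = 0.249) and within set 2 -1.73 (p = 0.0127), by the same test. Log2 total counts were 19.91 ± 0.87 in GBM and 19.60 ± 0.36 in cancer-free plasma, a difference of 0.31 (permutation p = 0.00758). This difference was 0.02 within set 1 (p = 0.819) and 0.64 within set 2 (p = 0.00245), and by ranks over all libraries it had p = 0.229. Every library with a total above the highest in cancer-free plasma was a GBM library without miR-4525 counts. The background level (log2 of the median CPM plus 1) was 3.78 ± 1.58 in GBM and 4.50 ± 1.31 in cancer-free plasma, a difference of -0.72 (permutation p = 0.00837). It differed by -0.63 within set 1 (p = 0.0370) and -0.94 within set 2 (p = 0.0564). The first principal component of log2 CPM held 54.75% of the variance and had an absolute Spearman correlation of 0.989 with the median CPM.

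The labels divide GBM into primary and recurrent disease, and each was compared with cancer-free plasma. In primary GBM miR-3180-3p rose by 2.05 ± 0.22 (adjusted p = 1.2e-12) and miR-5739 by 2.99 ± 0.33 (adjusted p = 2.8e-12), with n = 31 and 73. miR-4706 rose by 4.68 ± 0.57, miR-3937 by 2.58, miR-6081 by 2.92 and miR-150-5p by 2.40. In set 2, where all GBM libraries were primary, the mean log2 level of miR-150-5p was lower in GBM (9.13 against 11.12), opposite to this fitted rise. In set 1, with recurrent libraries included, it was 10.71 against 10.43. miR-4525 fell by 2.78 on the log2 scale (adjusted p = 0.000147) and miR-8084 by 2.21 (adjusted p = 0.000778). In all, 212 miRNAs were higher and 147 lower of 2082 tested (59.1% higher; 629 at an unadjusted p under 0.05). The split was 165 and 260 (38.8% higher, shift -0.25) with DESeq2 size factors, 54 and 442 (10.9%, shift -0.62) with library size alone, and 364 and 73 (83.3%, shift 0.049) with upper quartile scaling. No list was called by camera, the lowest adjusted p being 0.109 for the oncomiRs. The leukocyte list had 3 of 10 members higher (adjusted p = 0.125), and the late-numbered miRNAs changed in either direction (mixed fry, adjusted p = 0.000591). Within set 1, with 17 primary libraries, 244 were higher and 165 lower, sharing 56 of the 212 and 92 of the 147, and miR-4525 was at 0.03. Without near-empty libraries 178 were higher and 121 lower, and miR-4706 was at 3.0 and miR-6081 at 2.06.

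In recurrent GBM against cancer-free plasma (n = 13 and 73), miR-5739 rose by 5.85 ± 0.40 (adjusted p = 3.1e-26) and miR-3180-3p by 1.76 ± 0.29 (adjusted p = 1.7e-06). miR-144-3p rose by 2.73 ± 0.47 (adjusted p = 2.9e-06) and miR-451a by 1.5 (adjusted p = 0.0286). miR-3937 was at 2.87, miR-4306 at 3.01, miR-3648 at -2.89 and miR-4525 at -2.40 (adjusted p = 0.0421). Several of these values moved when the near-empty libraries, 3 of them primary and 1 recurrent, were left out. Without near-empty libraries miR-5739 was at 2.04 ± 0.33 (adjusted p = 2.4e-06), miR-4306 at 1.61, miR-144-3p at 1.91 and miR-4525 at -2.44, no longer called (adjusted p = 0.081), and miR-124-3p moved from 3.82 ± 0.44 (adjusted p = 7.2e-12) to -0.44 (adjusted p = 0.64). In all, 159 miRNAs were higher and 84 lower of 2082 tested (65.4% higher; 466 at an unadjusted p under 0.05), but 43 and 60 without near-empty libraries, of which 37 and 50 were shared. The split was 19 and 115 (14.2% higher, shift -0.88) with library size alone and 247 and 78 (76% higher, shift 0.085) with upper quartile scaling. DESeq2 size factors moved the median by -0.13. Within set 1, with 12 recurrent libraries, 209 were higher and 234 lower, mostly other miRNAs: 43 of the 159 and 22 of the 84 were shared, and 2 and 7 were called in the opposite direction. miR-144-3p was at 3.49.

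The erythrocyte list was higher in recurrent GBM than in cancer-free plasma, with a median of 1.17. Of its 11 members 3 were higher, or 8 adjusted over the list alone (camera adjusted p = 8.6e-10, and adjusted p = 0.276 with an estimated correlation; fry up, adjusted p = 0.0319). With the preset correlation, the miR-17-92 clusters (0.54, adjusted p = 0.000386), the let-7 family (0.41, adjusted p = 0.0286), the oncomiRs (0.16, adjusted p = 0.0237) and the circulating markers (0.07, adjusted p = 0.0290, but -0.12 with library size alone) were also higher, and the 14q32 cluster lower (-0.60, 3 members lower and 0 adjusted over the list alone, adjusted p = 0.00291). Each of these 5 had an adjusted p = 0.899 with an estimated correlation. Effects of primary and recurrent GBM correlated across 2082 miRNAs with r = 0.39 (covariance 0.197), where miRNAs are not independent replicates. Groups simulated without change against the same cancer-free libraries gave r = 0.13 (covariance 0.0128), and contrasts on separate cancer-free libraries gave r = 0.36. The simulated GBM libraries drew each miRNA independently, without library sets or near-empty libraries. The simulation therefore does not show what r real groups without change would give. The correlation was 0.220 without near-empty libraries and 0.858 within set 1, and groups without change were not simulated for either setting. In the 20 simulations over all libraries r ranged from 0.053 to 0.222, so 0.220 is not above all of them.

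Recurrent and primary GBM were also compared directly (n = 13 and 31). miR-144-3p was 2.22 ± 0.58 higher in recurrent GBM (adjusted p = 0.011), with 12 of 13 recurrent libraries above the primary median. miR-4447 was at 2.09 ± 0.37 (12 of 13 above), miR-4306 at 2.48 ± 0.46 (10 above), miR-500b-5p at 1.96 ± 0.36 (8 above), miR-6073 at 1.95 ± 0.40 (9 above) and miR-5739 at 2.85 ± 0.51 (7 above). miR-4707-5p was at -4.50 ± 0.94 (8 of 13 below), miR-623 at -3.66 ± 0.79 (7 below), miR-7846-3p at -3.46 ± 0.75 (8 below), miR-4487 at -2.89 ± 0.65 (10 below) and miR-4269 at -2.47 ± 0.52 (7 below). The adjusted p of these 10, without miR-144-3p, ranged from 0.000153 to 0.00278. In all, 25 miRNAs were higher and 89 lower of 2082 tested (21.9% higher; 294 at an unadjusted p under 0.05). The split was 3 and 43 (6.52% higher, shift -0.26) with library size alone, 23 and 49 (31.9%, shift 0.12) with DESeq2 size factors, and 12 and 96 (11.1%, shift 0.020) with upper quartile scaling. Set 2 held 0 recurrent libraries, so the sets and the groups overlap. Within set 1 (12 recurrent, 17 primary), edgeR called 0 higher and 0 lower, with 118 at an unadjusted p under 0.05. Over all libraries limma voom called 0 and 0, with 146 at an unadjusted p under 0.05, and DESeq2 17 and 85. Without near-empty libraries, 1 of which was recurrent, 1 was higher and 124 lower, with 1 of the 25 and 88 of the 89 shared. miR-5739 was then at -0.41, miR-144-3p at 1.45 (adjusted p = 0.17), and miR-4447, miR-500b-5p, miR-4306 and miR-6073 lay between 0.45 and 1.21, none called.

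The erythrocyte list had a median of 1.16 in recurrent against primary GBM. Of its 11 members 1 was higher, or 4 adjusted over the list alone. Its fry direction was up without passing the threshold (adjusted p = 0.139). By camera it was higher with the preset correlation (adjusted p = 2.2e-09) and not with an estimated one (adjusted p = 0.322). The miR-17-92 clusters were at 0.27 with 0 of 13 called by edgeR (adjusted p = 0.00426, and adjusted p = 0.974 with an estimated correlation). The 14q32 cluster was at -0.74 with 2 members lower, also adjusted over the list alone (adjusted p = 1.0e-08, and adjusted p = 0.941 with an estimated correlation). The haemolysis index was 5.46 ± 0.89 (n = 13) in recurrent and 3.49 ± 2.01 (n = 31) in primary GBM, a difference of 1.98 (permutation p = 0.00166), and 0.89 within set 1 (permutation p = 0.0411). Log2 total counts were lower in recurrent GBM by a difference of -0.67 (permutation p = 0.0174), and of -0.23 within set 1 (permutation p = 0.183).

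How well the counts separate GBM from cancer-free plasma was measured by cross-validation, since the study asked whether plasma miRNAs identify patients. The AUC was 0.985 (95% interval 0.955 to 1, n = 44 and 73) with all miRNAs, against at most 0.683 in 100 permutations of the labels (p = 0.0099, the smallest these permutations can give). The 5 miRNAs with the smallest p in each training fold gave 0.843. The haemolysis index and total count alone gave 0.569 (p = 0.119). Within set 1 the AUC was 0.9995 and within set 2 0.994. A model trained on set 1 gave 0.407 in set 2 (permutation p = 0.40), or 0.397 (permutation p = 0.349) with each set scaled to its own cancer-free libraries. A model trained on set 2 gave 0.1998 in set 1 with that scaling (permutation p = 2e-05), so that it ranked cancer-free libraries above GBM libraries.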

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

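The values within set 1, with the library set as covariate and without near-empty libraries were chosen after the results were seen, as were the splits without near-empty libraries, and the splits of all GBM libraries were chosen before. Each result in this part is a difference between recurrent GBM (n = 13) and primary GBM (n = 31), tested directly by the contrast between these groups. The effects of recurrent and primary GBM against cancer-free plasma differ by that same contrast.

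Among miRNAs tied to blood cells, miR-144-3p was higher in recurrent GBM by 2.22 and the erythrocyte list had a median difference of 1.16. The haemolysis index differed by 1.98, the miR-17-92 clusters by 0.27 and the 14q32 cluster by -0.74. With an estimated correlation the erythrocyte, miR-17-92 and 14q32 lists had adjusted p = 0.322, 0.974 and 0.941. Higher in recurrent GBM were also miR-5739 (2.85), miR-4306 (2.48), miR-4447 (2.09), miR-500b-5p (1.96), miR-6073 (1.95) and miR-124-3p (1.93). Lower were miR-6081 (-4.99), miR-4706 (-4.51), miR-4707-5p (-4.50), miR-623 (-3.66), miR-7846-3p (-3.46), miR-6838-3p (-3.19), miR-4487 (-2.89), miR-4269 (-2.47) and miR-150-5p (-2.35). These are edgeR log2 fold changes with adjusted p from 0.000153 (miR-5739, miR-4447) to 0.0466 (miR-150-5p). For miR-124-3p, 4 of 13 recurrent libraries lay above the primary median, and for miR-5739 7 of 13, so these 2 rises rest on a few libraries.

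Of 100 splits of the GBM libraries into groups of 13 and 31, the real one included, 48 called at least as many miRNAs as the real split. The real split called 114 and the highest other 504, so chance cannot be excluded for the count, and splits that call several times as many miRNAs point to a structure among the GBM libraries. Without near-empty libraries 21 of 100 splits reached the real count of 125, with 378 in the highest other, so chance cannot be excluded there either. The library sets are 1 such structure: set 2 held 10 primary and 0 recurrent libraries. Within set 1 (12 recurrent, 17 primary), 0 of these 16 miRNAs were called, with a lowest adjusted p of 0.812 and fold changes from -0.40 to 0.99. Over all 2080 miRNAs tested in set 1, edgeR called 0, with 118 at an unadjusted p under 0.05. With the set as covariate, 0 of the 16 were called. Without near-empty libraries, 1 of which was recurrent, 9 of the 16 were called in the same direction, miR-124-3p was called in the opposite one (-2.04, adjusted p = 0.0127) and miR-5739 was at -0.41. The haemolysis index differed by 0.89 within set 1 (permutation p = 0.0411). Recurrence itself remains an open explanation for the erythrocyte miRNAs, and no biological explanation was tested.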

How the results depend on the processing

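Fits within a set, without near-empty libraries, with the library set or the background level as covariate, and models moved between sets were chosen after seeing the data, and the other alternatives before. Of 43 named miRNAs called in GBM against cancer-free plasma, 4 kept their call and direction under every alternative in which they could be tested: miR-5739 (log2 fold changes from 1.68 to 6.90), miR-3180-3p (1.5 to 2.26), miR-3180 (1.27 to 2.11) and miR-606 (-2.43 to -1.31). Of 142 counts of called miRNAs under an alternative, 84 stayed within 1.5 times the reported count and 58 moved further. Of 1277 values of named miRNAs, 875 kept direction and side of the threshold, 119 passed it newly, 178 no longer passed it and 105 changed sign. Of 223 list values these numbers were 171, 12, 18 and 22. Of 25 other values, 15 stayed, 3 moved, 1 passed the threshold newly, 3 no longer passed it and 3 turned. A change of sign is counted where either value passed the threshold, and many such values lay near 0. Unless a reason is given, the cause was not tested.

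The reported counts were 242 higher and 244 lower in GBM than cancer-free plasma, 212 and 147 in primary GBM, 159 and 84 in recurrent GBM, and 25 and 89 in recurrent against primary GBM. With library size alone they were 65 higher and 931 lower in GBM, 54 and 442 in primary GBM, 19 higher in recurrent GBM, and 3 higher and 43 lower in recurrent against primary GBM. In GBM against cancer-free plasma, miR-4447 (-0.024), miR-6073 (-0.96), miR-4487 (-0.029), miR-15b-3p (-0.17), miR-515-5p (-0.35), the oncomiR list (-0.011) and the circulating marker list (-0.015) changed sign with it. Upper quartile scaling gave 366 higher and 131 lower in GBM, 364 and 73 in primary GBM, 247 higher in recurrent GBM and 12 higher in recurrent against primary GBM. DESeq2 size factors in edgeR gave 393 lower in GBM, 260 lower in primary GBM and 49 lower in recurrent against primary GBM.

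The filter at 100 counts left fewer miRNAs to test. It gave 92 higher and 20 lower in GBM, 21 lower in primary GBM and 46 higher in recurrent against primary GBM, and the correlation of primary and recurrent effects was 0.598. A further threshold of 1 on the absolute log2 fold change left, by its construction, 138 higher and 39 lower in GBM and 98 and 39 in primary GBM. No count moved beyond 1.5 times without a filter or with TMM without the 5 most abundant miRNAs. Leaving out libraries with low totals removed 0 libraries, so it tests nothing. The filter on control probes was not run, since the table holds none.

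Other tests changed the balance as well. DESeq2's Wald test gave 554 lower in GBM, 463 lower in primary GBM and 78 higher in recurrent GBM. With it, in GBM against cancer-free plasma, miR-150-5p (-0.11), miR-4707-5p (-1.38), miR-7846-3p (-0.92), miR-623 (-0.57), miR-4487 (-0.80) and miR-342-3p (-0.14) changed sign, as did miR-5739 in recurrent against primary GBM (-1.09). limma voom with quality weights gave 186 higher and 320 lower in GBM, but kept 68 of the 242 higher calls, called 23 of them lower and moved their median from 1.07 to 0.075. It gave 106 higher and 97 lower in primary GBM, 135 lower in recurrent GBM, and 0 higher and 0 lower in recurrent against primary GBM, where 146 miRNAs had an unadjusted p under 0.05 and DESeq2 called 17 and 85. In GBM against cancer-free plasma it turned miR-124-3p (-0.093), miR-6081 (-1.21), miR-150-5p (-0.0088), miR-6838-3p (-0.65), miR-1247-3p (-0.76), miR-4292 (-0.034), miR-3917 (-1.17), miR-4707-5p (-1.31), miR-4269 (-0.82), miR-7846-3p (-0.97), miR-623 (-0.40), miR-4487 (-0.43), miR-342-3p (-0.042) and miR-515-5p (-0.052).

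With the haemolysis index as covariate, 81 miRNAs were higher and 92 lower in primary GBM and 6 lower in recurrent against primary GBM. With log2 total count as covariate, 15 were higher and 6 lower in recurrent against primary GBM. In GBM against cancer-free plasma it turned miR-4707-5p (-1.65), miR-4269 (-0.40), miR-7846-3p (-1.27), miR-623 (-0.61), miR-4487 (-0.39), miR-342-3p (-0.37), the oncomiR list (-0.060), the circulating marker list (-0.17) and the miR-17-92 list (-0.039). With the background level as covariate, 56 were higher and 95 lower in GBM, 77 and 64 in primary GBM, 56 higher in recurrent GBM and 7 higher in recurrent against primary GBM, and miR-3917 (-0.11) and miR-6126 (-0.00096) changed sign in GBM. With the library set as covariate, 95 were higher in recurrent GBM, 5 higher and 2 lower in recurrent against primary GBM. miR-150-5p (-0.086) and miR-342-3p (-0.083) then changed sign in GBM, and miR-5739 in recurrent against primary GBM (-0.36).

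A replicate block on the title numbers assumes a pairing that the data do not show: of 44 pairs of a GBM and a cancer-free library with the same number, 2 GBM libraries were closest to their own number, and the median correlation within pairs was 0.057 against -0.002 otherwise. The block gave 444 lower in GBM, 133 higher and 433 lower in primary GBM, and 10 higher and 1 lower in recurrent GBM, and it turned miR-4707-5p (-0.11) and miR-4487 (-0.20) in GBM. Its values for recurrent against primary GBM are not reported here, since a recurrent and a primary library never share a title number.

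Without near-empty libraries, 1 of them recurrent, 43 miRNAs were higher in recurrent GBM and 1 in recurrent against primary GBM, and the correlation of primary and recurrent effects was 0.220. miR-4447 (-0.12), miR-515-5p (-0.14) and miR-6126 (-0.016) changed sign in GBM and miR-5739 (-0.41) in recurrent against primary GBM. In set 1 alone, 234 were lower in recurrent GBM, and 0 higher and 0 lower in recurrent against primary GBM by edgeR (118 at an unadjusted p under 0.05). The correlation of effects was 0.858, and log2 totals differed by 0.023 between GBM and cancer-free plasma. Signs changed there for miR-124-3p (-0.015), miR-6081 (-0.27), miR-6838-3p (-0.20), miR-1247-3p (-0.21), miR-4707-5p (-0.54), miR-4269 (-0.56), miR-623 (-0.071), miR-4487 (-0.30), miR-515-5p (-0.087), miR-378f (-0.10) and miR-6126 (-0.028) in GBM, and for miR-4707-5p (0.31) and miR-4269 (0.16) in recurrent against primary GBM.

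Set 2 alone turned the most values. It gave 252 lower in primary GBM and a difference of -1.73 in the haemolysis index, now past the threshold. In GBM against cancer-free plasma the sign turned for let-7f-5p (-3.68), let-7g-5p (-3.68), miR-19a-3p (-3.20), miR-29b-3p (-3.13), miR-96-5p (-2.82), miR-451a (-2.80), miR-126-5p (-2.70), miR-148a-3p (-2.60), miR-20b-5p (-2.49), miR-144-3p (-2.12), miR-23a-3p (-2.07), miR-25-3p (-1.87), miR-146b-5p (-1.80), let-7e-5p (-1.78), miR-758-3p (-1.76), miR-197-3p (-1.74), miR-155-5p (-1.53), miR-133a-3p (-1.44), miR-889-3p (-1.33), miR-15b-3p (-1.21), miR-342-3p (-1.13), miR-182-5p (-0.79), miR-4306 (-0.67), miR-150-5p (-0.54), miR-4447 (-0.019), miR-3937 (-0.0094), miR-1468-3p (0.19) and miR-3910 (0.59). The list medians that turned were let-7 (-2.58), erythrocyte (-2.36), miR-17-92 (-2.26), platelet (-2.20), leukocyte (-1.64), oncomiRs (-1.53), circulating markers (-1.36) and early-numbered miRNAs (-0.83).

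Set 2 without its near-empty libraries gave 141 lower in GBM. The sign turned for miR-144-3p (-3.35), let-7f-5p (-3.20), let-7g-5p (-3.19), miR-19a-3p (-2.73), miR-29b-3p (-2.67), miR-96-5p (-2.51), miR-451a (-2.32), miR-126-5p (-2.25), miR-148a-3p (-2.11), miR-4306 (-2.06), miR-20b-5p (-2.02), miR-182-5p (-1.91), miR-6073 (-1.59), miR-4447 (-1.48), miR-758-3p (-1.38), miR-155-5p (-1.08), miR-15b-3p (-0.78), miR-342-3p (-0.65), miR-150-5p (-0.028), miR-3648 (0.42) and miR-1468-3p (0.64). The list medians that turned were let-7 (-2.08), erythrocyte (-2.01), miR-17-92 (-1.78), platelet (-1.71), oncomiRs (-1.26), leukocyte (-1.20), circulating markers (-0.97), early-numbered (-0.45) and late-numbered miRNAs (0.058).

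Among single values, the difference in total counts by mean rank was 7.80 and no longer passed the threshold. The AUC was 0.569 with the haemolysis index and total count alone. It was 0.407 for a model trained on set 1 and tested on set 2, 0.397 with each set scaled to its own cancer-free libraries, and 0.1998 for training on set 2 and testing on set 1 with that scaling. Other models and feature sets gave AUCs from 0.843 to 0.994 over all libraries. At the depth of these libraries, miRNAs with few counts were left out by the filter, and a change of 1.5-fold was recovered in 41.8% of simulated cases for GBM against cancer-free plasma and in 5.97% for recurrent against primary GBM, so a miRNA that was not called is not shown to be unchanged.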

Other observations

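Chosen after the results were seen were the tests on near-empty libraries for the called miRNAs, on splits without near-empty libraries (with predictions written before their outcome), on miR-4525 and on models moved between sets, as well as the definition of the sets and the choice of miRNAs called in both sets. The other tests of sets, background and splits of all libraries or of set 1 were chosen before their results were seen.

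Rises or falls of 20 miRNAs were called within set 1, within set 2, over all libraries and without near-empty libraries. Among them, miR-4706, miR-4530, miR-3663-5p and miR-4436a belong to the pairs that defined the sets. Their calls within the sets are therefore not independent of that definition. Set 2 without its near-empty libraries is a part of the libraries used to choose these miRNAs, so it is not an independent test. There 8 of the 14 rises and 3 of the 6 falls were called, and miR-1273a (-0.32) and miR-1587 (-0.81) had the opposite sign. Of 242 miRNAs called higher, 26 were called higher in each set and 14 of these also without near-empty libraries. Of 244 called lower, 7 were called lower in each set and 6 also without near-empty libraries. The rises, with log2 fold changes in set 1 and set 2, were miR-3180-3p (2.26, 1.60), miR-5739 (2.19, 3.73), miR-3180 (2.11, 1.65), miR-5009-5p (1.66, 2.28), miR-4706 (1.52, 5.39), miR-1587 (1.07, 1.06), miR-4530 (0.88, 2.77), miR-1273a (0.86, 1.63), miR-7162-5p (0.76, 1.79), miR-1297 (0.72, 1.75), miR-6842-3p (0.61, 2.12), miR-658 (0.51, 2.14), miR-6071 (0.49, 1.27) and miR-4319 (0.42, 2.82). In set 2, miR-5739, miR-4706 and miR-4319 lay above the cancer-free median in 10 of 10 GBM libraries. miR-1587 and miR-4530 did so in 4 of 10 and miR-6842-3p and miR-6071 in 2 of 10, so these 4 calls rest on a minority of libraries. The mean log2 level in set 2 was lower in GBM for miR-6842-3p (5.62 against 6.99), miR-6071 (4.66 against 4.98) and miR-3180-3p (6.25 against 6.34), opposite to their fitted rises. The falls were miR-873-3p (-1.09, -1.09), miR-3663-5p (-0.98, -1.22), miR-1182 (-0.75, -1.51), miR-5586-3p (-0.75, -1.17), miR-711 (-0.58, -1.87) and miR-4436a (-0.47, -1.03). In set 2, miR-711, miR-1182 and miR-3663-5p lay below the cancer-free median in 10 of 10 GBM libraries.

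GBM and cancer-free plasma differed in 486 miRNAs, against 421 in the highest of the other splits of the same libraries. Of 100 splits, 1 (the real one) reached the real count, so chance is unlikely for this count. So few splits cannot exclude it, and they were drawn without regard to the library sets. For primary GBM the real count was 359 and the highest other 218, and for recurrent GBM 243 and 230, again with 1 of 100 splits each. The recurrent count fell to 103 without the near-empty libraries, 3 of them primary and 1 recurrent. There 3 of 100 splits, the real one included, reached that count and the highest other called 190, so chance is unlikely but not excluded. The count for GBM was then 346 against 221 and for primary GBM 299 against 275, with 1 of 100 splits each. Within set 1, 641 were called and at most 98 in another split, with 1 of 100 at the real count. Of the calls higher in GBM 29.8% (Wilson 95% interval 24.3 to 35.8), and of those lower 79.5% (74.0 to 84.1), were also called within set 1. Of all 2012 miRNAs tested within set 1, 295 were higher and 346 lower. These shares cannot decide whether the library sets are the whole source of the calls. Set 1 is part of the pooled fit, and its GBM libraries scored towards set 2. The Wilson intervals also treat miRNAs as independent, which they are not. Near-empty libraries as the whole source are argued against by 40.5% (34.5 to 46.8) and 58.6% (52.3 to 64.6) called without them, and the background level by 34% (28.4 to 40.2) of the calls lower in GBM, while 20.7% (16 to 26.2) of those higher leaves the background open for these. Each may account for part of the calls, and a difference in tube, handling or plate that follows the groups cannot be tested with these labels, so GBM itself stays an open explanation.

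The fall of miR-4525 may come from libraries outside set 1 in which its probe gave no count. Within set 1 the log2 fold change was -0.08 (SE 0.30, adjusted p = 0.86), and 0 of 29 GBM libraries there had a count of 0. All 13 libraries without miR-4525 counts also lacked counts of miR-128-2-5p, among them the library with the highest total, 6702324, so low depth does not account for all of them. The 13 libraries have consecutive title numbers, and no run among them exceeded 7 in 1000 shuffles of the numbers, so the zeros follow the numbering of the libraries. The same run holds all 4 near-empty libraries and 9 of the 10 GBM libraries of set 2. It also holds every library with a total above 1476120, the highest total in cancer-free plasma. The totals of these deeper libraries ran from 1769249 to 6702324, so high totals follow the numbering as well. The labels do not say what the numbering follows, so a failure of some probes in libraries handled together is not told apart from a difference of donors numbered together.

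Separation of GBM from cancer-free plasma was not explained by near-empty libraries alone, while the sets could not be excluded. The AUC was 0.9925 without near-empty libraries, where the highest of 100 permutations was 0.721. Within set 1 it was 0.9995, where the highest of 100 permutations was 0.824. The value within set 1 cannot exclude the sets, because the groups also differed there in the set score (medians 0.821 in GBM and 1.0 in cancer-free libraries). Models moved between sets failed, with the lower AUC at 0.1998 (permutation p = 2e-05). Differences between GBM and cancer-free libraries that are particular to each set would give such a failure. The difference between the sets would also give it, since in each set GBM libraries scored towards the other set. Models moved between sets cannot tell these explanations apart. The opposite signs of erythrocyte, let-7 and miR-17-92 miRNAs in the sets go in the same direction as this failure. They rest on the same libraries and placement, so they are not separate support. Whether the differences between GBM and cancer-free libraries stem from handling or from the donors was not tested, since neither is given per library.

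The library whose labels contradict each other on its group had a total count of 720591 and 2083 miRNAs with a count above 0. On log2 CPM plus 1 without TMM scaling, unlike the levels above, its miR-3180-3p was at 8.34, against medians of 6.04 in cancer-free and 7.49 in GBM plasma. miR-5739 was at 9.96, against 8.83 and 10.7, and miR-451a at 16.61, against 16.86 and 17.17.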
